A study of Daphnia magna with 335 samples.

How the data were processed

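The samples were 335 TempO-Seq libraries of whole Daphnia magna, each from a pool of 5 animals exposed for 24 h, per the labels' protocols. Per the submitters' processing notes, bcl2fastq was used, with no version given; the program that assigned reads to probes, its version and its settings are not given in the sources used here. The authors deposited 1 table of raw counts per probe for the whole series, in whole numbers, with no scaling per the file headers and values. They also deposited, for each of the 12 chemicals, a table of log2 values of its treated libraries and DMSO pools, and 2 such tables of the DMSO pools and the control QA libraries. Checked against the counts, every deposited log2 value was log2(count + 1), within 1e-04, except in the table of 3,4-dichlorophenyl isocyanate, where 18 columns held log2 values and 11 held the counts themselves. These tables are not scaled for the total of a library. Every column was matched to a sample by its name; columns matched to no sample numbered 0.

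Concentrations were taken from the concentration line of the chemicals' own tables, which pairs each column with a value in µM. Level codes D1 to D8 in the labels run from the highest to the lowest. In the table of 3,4-dichlorophenyl isocyanate that line stands 1 column out of step for 7 treated libraries and 1 DMSO pool, so the level codes of the labels were used and that line only as an alternative. The highest concentration of fexofenadine is 34.2 µM in its table and 32.2 µM in the exposure protocol; the table's value is used here. The labels name 1 chemical 4-chlorophenyl methyl sulfoxide and the design text the sulfone; the labels' name is used here.

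All tests ran on the counts as deposited. Each chemical was fitted alone with the 6 DMSO pools of its exposure, in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter on low counts and the quasi-likelihood F test; 1379 to 1487 probes were left per chemical. A test of all 8 levels against DMSO, a test of a linear trend over the level code among treated libraries, and 8 tests of single levels were made, each with Benjamini-Hochberg adjustment over probes and a threshold of 0.05 on the adjusted p. The 96 single-level tests were adjusted within each level. Fold changes are log2 with their standard errors, and CPM are scaled by the TMM factors. Libraries under 10% of the median total of their exposure were to be left out; there were 0. No 2 libraries held identical counts, and the highest correlation of log2 CPM between 2 libraries was 0.992. DESeq2 1.42.0 was the other count model, and limma 3.58.1 was run on the chemicals' own log2 tables.

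Benchmark concentrations were computed in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) on log2 CPM with a prior count of 2. Linear, power, exponential and Hill curves and a constant were fitted to each called probe, the one with the lowest Akaike criterion was kept, and the concentration was read where it departed by 1 SD of the DMSO pools; chemicals with fewer than 20 such values were left out. On simulated curves with true values of 0.5, 5 and 20 µM the median estimates were 0.619, 5.08 and 21.9 µM. The quartiles of single estimates were 0.670 and 2.03, 0.471 and 1.77, and 0.590 and 1.62 times the true value. These simulated curves had a single saturating shape and equal spread in all pools. Figures were drawn with matplotlib 3.10.9. The count tests were tested on simulated counts with 200 changed probes per chemical: for fipronil amide, with the change at the highest concentration alone, 35.8% of probes changed 1.5-fold, 46.3% of those changed 2-fold and 84.8% of those changed 3-fold were recovered, and 3.48% of calls were false. Over the 12 chemicals, recovery of 1.5-fold changes at the highest concentration alone ran from 1.49% to 37.3%, of 2-fold changes from 20.9% to 70.2% and of 3-fold changes from 65.2% to 86.4%.

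The replicate letters A, B and C are shared by treated and DMSO pools. The protocol in the labels says that pools were made within each of 3 plates. That the letters name these plates is an inference, and on it the letter was put in the model as an alternative. Between libraries of the same letter, the mean correlation across probes of deviations from the group means was positive in every chemical. It ran from 0.0119 for Metribuzin-DA to 0.283 for Metolachlor OA, so the data alone do not show a clear pairing in all of them. The means between letters, -0.138 to -0.00598, follow from taking deviations from group means and add no information. The fits without the letter are reported first, and counts with the letter in the model are given where they differ by more than 1.5 times.

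The groups, tests, alternatives and the rule for named probes were fixed before the data were examined; those added later are named as such. The rule took, per chemical, the probes called over all levels, each at its called level with the largest fold change and with every treated library of that level on that side of the DMSO mean of log2 CPM: the 12 highest and 12 lowest where 100 or more were called, otherwise the 5 highest and 5 lowest, plus the probes called for the most chemicals. The reference table for Daphnia magna (assembly ASM2063170v1.1, 28335 genes) matched 0 of the 1988 gene identifiers, so no gene names were used, the gene lists fixed beforehand were not run, and at most 2 probes that rose and 2 that fell are printed per comparison. For 3,4-dichlorophenyl isocyanate 3 that rose are printed, 1 of them chosen after its values were seen. So are 3 for 2-tert-butyl-4-methoxyphenol, 1 of them added afterwards for its rise with Metribuzin-DA. Of the gene identifiers, 329 had 2 or more probes. Alternatives were DESeq2's size factors, DESeq2, no filter on low counts, the replicate letter in the model, both chemicals of an exposure in 1 fit, the CON pools alone, the chemicals' own log2 tables, each replicate left out in turn, and the trend without D1 or D8.

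Folds against a group at 0 counts are lower bounds against 3 counts over the group; with 1 to 3 counts the ratio has its exact 95% interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Pools came from separate wells and animals of 1 exposure, so p-values measure the spread between pools within that exposure, not between repeated exposures. Totals of 118094 to 1171681 counts limit what can be seen in probes of few counts.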

Results

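Transcripts were measured in whole Daphnia magna, a small freshwater crustacean used in water testing, after 24 h in water with 1 of 12 chemicals. The chemicals were contaminants of Great Lakes tributaries for which little toxicity data existed, and the series asked at which concentrations transcripts respond, so that the contaminants can be ranked. Each chemical was given at 8 concentrations of a serial dilution, coded D1 (highest) to D8 (lowest), and 2 chemicals shared each of 6 exposures and that exposure's 6 pools in solvent (dimethyl sulfoxide, DMSO). Each library came from a pool of 5 animals, with 3 pools per concentration. There were 335 libraries: 287 treated, 36 DMSO pools and 12 libraries named control QA in the labels. Of the 96 combinations of chemical and concentration, 95 held 3 pools and 1 held 2, since replicate C of 3,4-dichlorophenyl isocyanate at 66.67 µM was not analysed here.

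The assay, TempO-Seq, counts pairs of detector oligonucleotides joined on their target transcript, so each value is a count of a probe. The table held 2378 probes for 1988 gene identifiers. Total counts per library ran from 118094 to 1171681, with a median of 619413. The 10 most counted probes of a library held 22.1% to 44.0% of its counts in 334 libraries and 90.8% in the remaining one, replicate C of 3,4-dichlorophenyl isocyanate at 21.1 µM. The files do not pair the gene identifiers with gene names, so probes are given by identifier, a few per chemical.

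**Figure D1:**
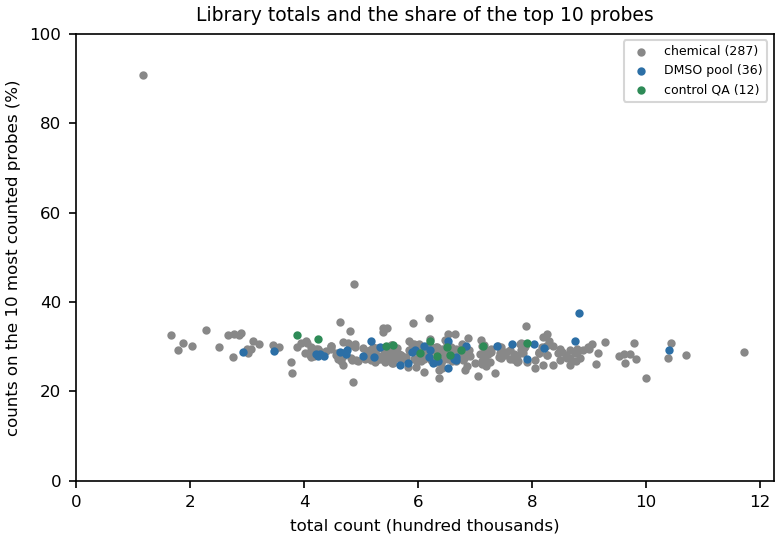
Total count (x axis, in units of 100000 counts) against the percent of counts held by the 10 most counted probes (y axis), 1 point per library. All but 1 library lie between 22.1% and 44.0%; the library at 90.8% is replicate C of 3,4-dichlorophenyl isocyanate at 21.1 µM, which also has the lowest total, 118094.

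The first comparison asked, for each chemical, which probes changed at any concentration against the DMSO pools of the same exposure. The chemicals fell into 5 with 50 or more changed probes and 7 with fewer than 10. 2-tert-Butyl-4-methoxyphenol changed 680 of 1471 probes, cis-nonachlordane 173 of 1424, fipronil amide 100 of 1390, 3,4-dichlorophenyl isocyanate 73 of 1454 and Metribuzin-DA 71 of 1487, at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 717, 235, 166, 119 and 261 probes of these chemicals. In a test over the 8 treated levels alone, 399 probes of 2-tert-butyl-4-methoxyphenol, 122 of cis-nonachlordane, 91 of fipronil amide and 75 of 3,4-dichlorophenyl isocyanate were called, higher or lower with concentration, for a linear trend over the level code. For Metribuzin-DA the same edgeR trend test called 0 of 1398 probes, with 171 at an unadjusted p under 0.05 and 0 by DESeq2.

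**Figure D2:**
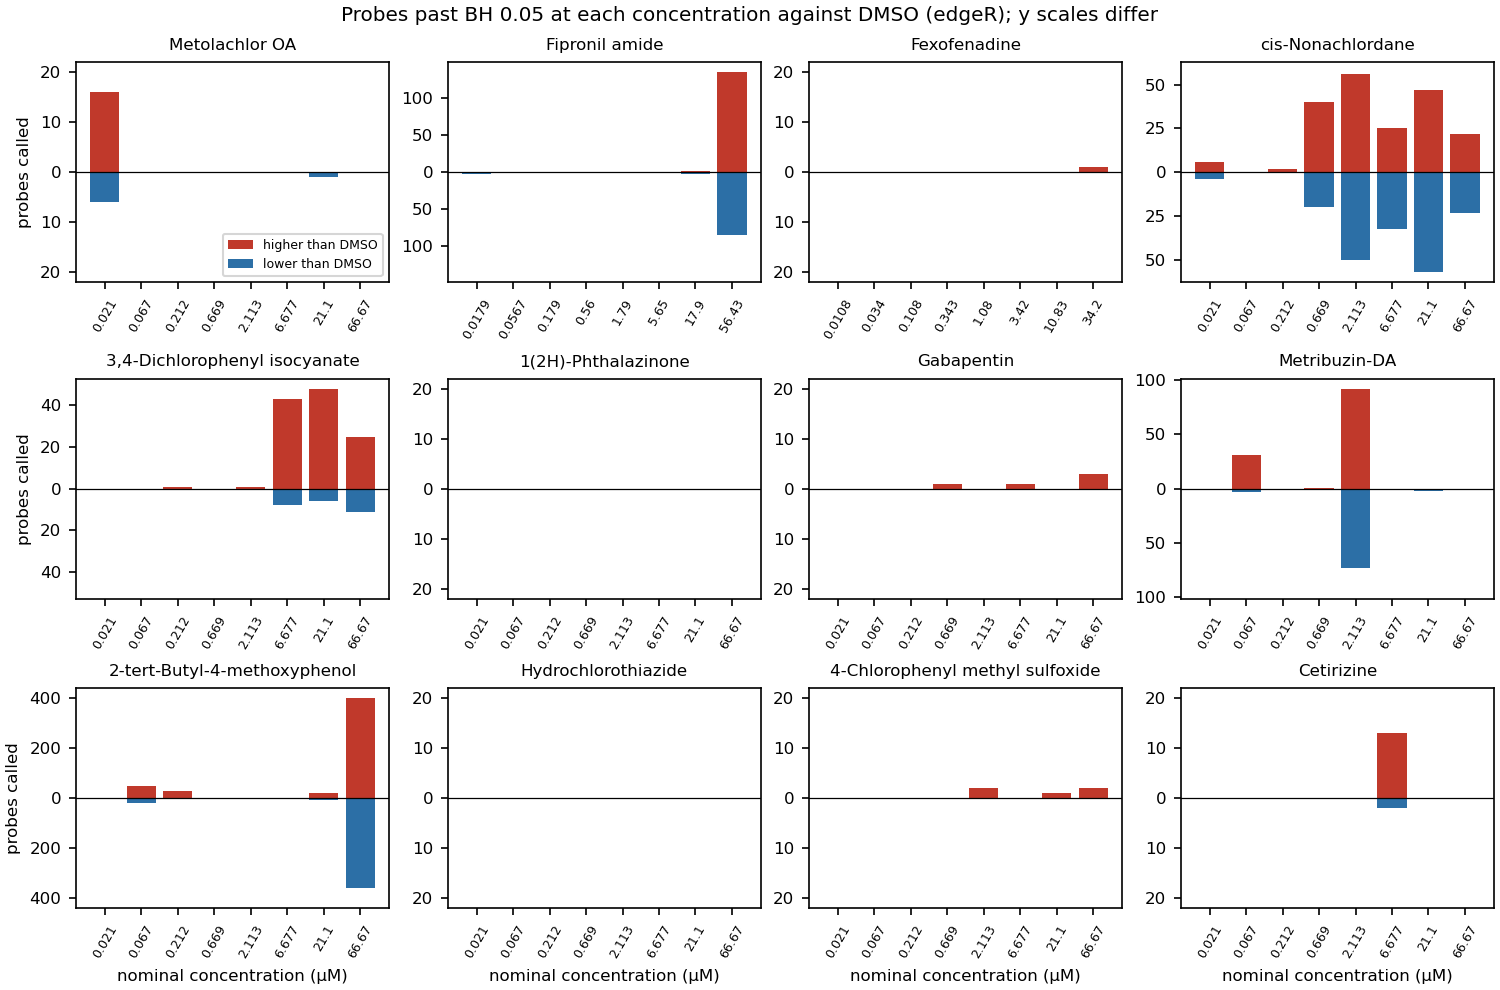
Number of probes higher and lower than the DMSO pools (y axis, counts; scales differ between panels) at each nominal concentration (x axis, µM, log scale), 1 panel per chemical. Calls of 2-tert-butyl-4-methoxyphenol (401 higher, 360 lower) and fipronil amide (135 higher, 84 lower) peak at the highest concentration, those of cis-nonachlordane spread over its 5 highest, and those of Metribuzin-DA stand at 2.113 and 0.067 µM.

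2-tert-Butyl-4-methoxyphenol, a phenolic antioxidant used in food, changed probes mainly at its highest concentration, 66.67 µM, where 401 were higher and 360 lower than in DMSO. Dapma7bEVm010966_96832 rose from 23.8 ± 5.58 CPM (counts scaled to the library total; SD, n = 6) in DMSO to 1540 ± 73.1 (n = 3), a log2 fold change of 5.97 ± 0.29 (SE; adjusted p = 1.47e-14, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Dapma7bEVm002921_97205 rose from 106 ± 60.7 to 5268 ± 2088 CPM (log2 fold change 5.63 ± 0.41). Dapma7bEVm005357_97477 stood at 51.9 ± 10.3 CPM in DMSO and at 0 counts in all 3 pools at 66.67 µM, at least 35.6-fold lower against a floor of 3 counts over the group. Dapma7bEVm005157_96399 fell from 95.7 ± 29.9 CPM to 1 count in the 3 pools, a ratio of 190 (95% counting interval 34.1 to 7509).

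At 21.1 µM of 2-tert-butyl-4-methoxyphenol 19 probes were higher and 6 lower, and at 6.677 µM 1 was higher. A further group of calls stood at low concentrations, with 30 higher and 3 lower at 0.212 µM and 49 higher and 21 lower at 0.067 µM. Those at 0.067 µM ran mostly against those at 66.67 µM: 43 probes were called at both in opposite directions, 2 were higher at both and 5 lower at both. Independent lists would share 13.4 higher and 5.14 lower probes, and no such value was computed for the opposite ones. Unchanged counts simulated against the same DMSO pools shared 0 in each of 20 simulations. Since they hold no changed probe, these simulations, here and below, do not show what shared DMSO pools add to long lists of calls. With the CON pools as controls for 1 level and the XtraC pools for the other, 0 probes were shared in the same direction. Those called at both in the same direction numbered 7. With the replicate letter in the model there were 12, in DESeq2 19, without replicate A 15, without the filter on low counts 4, with both chemicals of the exposure in 1 fit 3, without libraries under 50% of the median total 2, and without B, without C or against the CON pools alone 0. Over the levels, 245 probes rose with concentration and 154 fell; without the highest concentration the trend test called 9 and the any-level test 30. Leaving out 1 replicate gave 482 or more calls at 66.67 µM, and 318 to 698 over all levels, 42 to 417 in the trend test. In limma on the chemical's own table, which is not scaled for the library total, 84 probes were higher and 115 lower at 66.67 µM. The calls at 0.212 and 0.067 µM each went to 0 without replicate B, without replicate C, or against the CON pools alone. They were 109 and 220 without replicate A, against 33 and 70 with all pools, 65 and 7 without libraries under 50% of the median total, and with the replicate letter in the model 74 at 0.212 µM. DESeq2 called 95 and 99, and without the filter on low counts 15 and 44 were called. Limma on the chemical's own table called 0 at 0.212 µM and 12 at 0.067 µM, all of them lower.

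Fipronil amide, a breakdown product of the insecticide fipronil, raised 135 probes and lowered 84 at its highest concentration, 56.43 µM. Dapma7bEVm010649_96442 rose from 1618 ± 410 CPM (SD, n = 6) to 18432 ± 2732 (n = 3), a log2 fold change of 3.51 ± 0.43 (SE; adjusted p = 2.06e-06, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Dapma7bEVm002921_97205 rose from 82.5 ± 28.2 to 798 ± 181 CPM (log2 fold change 3.27 ± 0.30). Dapma7bEVm011534_97824 fell from 54.6 ± 8.41 CPM to 3 counts over the 3 pools, a ratio of 29.7 (95% counting interval 10.2 to 144), and Dapma7bEVm005157_96399 fell from 88.5 ± 24.7 to 7.54 ± 2.39 CPM (log2 fold change -3.53 ± 0.33).

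At 17.9 µM of fipronil amide 2 probes were higher and 2 lower, and no lower concentration gave more than 3 calls. Dapma7bEVm011534_97824 was among those still called at 17.9 µM, at a log2 fold change of -1.89 ± 0.35, whereas Dapma7bEVm002921_97205 stood at 0.49 ± 0.32 there and was not called. Of the 100 probes called over all levels, 63 were higher and 37 lower, and with the replicate letter in the model 175 were called. The trend test called 59 rising and 32 falling probes, and 3 without the highest concentration. In limma on the chemical's own table, which is not scaled for the library total, 39 probes were higher and 68 lower at 56.43 µM. Against the CON pools alone 122 probes were called there, without replicate A 82 and without B 141; leaving out 1 replicate gave 24 to 80 over all levels and 12 to 97 in the trend test.

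cis-Nonachlordane, a constituent of the organochlorine insecticide chlordane, changed probes over its 5 highest concentrations. From 66.67 to 0.669 µM the counts of higher and lower probes were 22 and 23, 47 and 57, 25 and 32, 56 and 50, and 40 and 20, and at 0.212 µM 2 probes were higher. Dapma7bEVm011534_97824 stood at 174 ± 43.1 CPM (SD, n = 6) in DMSO and at 4.84 ± 3.19 (n = 3) at 6.677 µM, a log2 fold change of -5.20 ± 0.54 (SE; adjusted p = 4.31e-07, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Its log2 fold changes at the other 4 of these concentrations were -4.57, -4.53, -3.50 and -2.82, and at 0.212 µM it stood at 0.44 ± 0.34 and was not called. Dapma7bEVm001964_97694 fell from 3187 ± 616 to 166 ± 21.7 CPM at 21.1 µM (log2 fold change -4.26 ± 0.37). At 0.212 µM it was higher than in DMSO, at 8072 ± 3374 CPM (log2 fold change 1.34 ± 0.28, adjusted p = 0.0459).

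Dapma7bEVm001285_98069 rose with cis-nonachlordane from 12.4 ± 2.69 CPM to 389 ± 133 at 6.677 µM, a log2 fold change of 4.95 ± 0.64. It was called at each of the 6 highest concentrations, with log2 fold changes between 3.86 at 0.212 µM and that value, and stood at 1.61 ± 0.79 at 0.067 µM without a call. Calls at 21.1 and 2.113 µM, 10-fold apart, overlapped: 33 probes were higher at both, 34 lower at both and 0 opposite. Independent lists would share 1.85 higher and 2.00 lower. In each of 20 simulations of unchanged counts against the same DMSO pools 0 were shared. Without any changed probe these do not test shared controls for lists this long. With the CON pools as controls for 21.1 µM and the XtraC pools for 2.113 µM, 10 higher and 14 lower probes were shared, and 9 and 14 with these exchanged. In both directions together 67 were shared, 34 without replicate A, 18 without B, 9 without C and 27 against the CON pools alone.

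Of the 173 probes called for cis-nonachlordane over all levels, 84 were higher and 89 lower, and the trend test called 45 rising and 77 falling. In limma on the chemical's own table, not scaled for the library total, most calls at each of the 5 highest concentrations were higher, with 24 higher and 5 lower at 66.67 µM and 102 and 12 at 21.1 µM. With the replicate letter in the model 272 were called over all levels, 72 at 66.67 µM, 95 at 6.677 µM and 93 at 0.669 µM. Leaving out 1 replicate gave 24 to 91 over all levels and 46 to 89 in the trend test, and the CON pools alone 115 over all levels; without replicate C, 10 to 23 probes were called at each of the 5 highest concentrations. At the lowest concentration, 0.021 µM, 10 probes were called, 19 with the replicate letter in the model; without replicate B, without replicate C, against the CON pools alone or without the filter on low counts the edgeR count was 0, with 205 probes at an unadjusted p under 0.05 and 25 called by DESeq2 when all pools were used.

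3,4-Dichlorophenyl isocyanate, an intermediate in the making of phenylurea herbicides, changed probes at its 3 highest concentrations: 25 higher and 11 lower at 66.67 µM (2 pools), 48 and 6 at 21.1 µM, and 43 and 8 at 6.677 µM. Dapma7bEVm003956_96116, chosen after its values were seen, was nearly silent in DMSO (3 counts in the 6 pools) and reached 142 ± 53.7 CPM (SD, n = 3) at 6.677 µM, a ratio of 183 (95% counting interval 62.6 to 887). The ratio was 82.8 (28.3 to 401) at 21.1 µM and 34.2 (11.7 to 166) at 66.67 µM. Dapma7bEVm002921_97205 rose from 63.8 ± 38.5 to 780 ± 327 CPM (n = 2) at 66.67 µM, with log2 fold changes of 3.61 ± 0.54, 3.26 ± 0.53 and 2.51 ± 0.50 at the 3 concentrations (SE; adjusted p at most 0.00293, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Dapma7bEVm011534_97824 stood at 91.9 ± 45.1 CPM in DMSO and at 0 counts in both pools at 66.67 µM, at least 27.5-fold lower, and Dapma7bEVm008403_97506 fell from 101 ± 52.2 CPM to 2 counts, a ratio of 45.0 (12.5 to 372).

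Replicate C of 3,4-dichlorophenyl isocyanate at 21.1 µM weighed on these counts, since a single probe, Dapma7bEVm027952_95783, held 74.8% of its 118094 counts. That probe ranked highest by the rule for named probes, with a log2 fold change of 9.52 ± 1.29 at 21.1 µM, and without this library its value was 0.21 (adjusted p = 0.870, edgeR quasi-likelihood with Benjamini-Hochberg adjustment; 3.55e-05 with it). Without it 64 probes were called at 66.67 µM (40 higher, 24 lower), 31 at 21.1 µM (28 and 3) and 76 at 6.677 µM (61 and 15). Calls at 21.1 and 6.677 µM shared 21 higher and 2 lower probes, against 1.42 and 0.0330 for independent lists. The 20 simulations of unchanged counts shared 0 and, without any changed probe, do not test shared controls. With CON pools as controls for 21.1 µM and XtraC pools for 6.677 µM, 7 higher and 1 lower were shared, and 5 and 1 with these exchanged. In both directions together 23 were shared, 12 without replicate B, 7 without C, 9 against the CON pools alone, 4 in limma on the chemical's own table and 41 with the replicate letter in the model. Over all levels 62 probes were higher and 11 lower, and the trend test called 52 rising and 23 falling. In this chemical's own deposited table, the concentration row puts 7 treated libraries of replicate C and 1 DMSO pool 1 step away from the level in their labels; with that row 73, 28 and 15 probes were called at the 3 concentrations. With the replicate letter in the model 81 were called at 6.677 µM. In limma on that table, not scaled for the library total, 1 probe was higher and 6 lower at 66.67 µM, 15 and 1163 at 21.1 µM, and 4 and 1 at 6.677 µM. Without replicate B the 3 counts were 4, 84 and 25, without C 17, 10 and 13, and over all levels 40 and 16, with 1 and 39 in the trend test. Against the CON pools alone the counts at the 3 concentrations were 12, 29 and 20. DESeq2 called 27 higher and 35 lower at 66.67 µM, so there the larger share was lower. The falls of Dapma7bEVm011534_97824 and Dapma7bEVm008403_97506 at 66.67 µM (adjusted p = 0.0485 and 0.0489) missed the threshold without replicate B, without C, against the CON pools alone and without the filter on low counts.

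Metribuzin-DA, a breakdown product of the herbicide metribuzin, changed 92 probes upward and 73 downward at 2.113 µM and 31 upward and 3 downward at 0.067 µM, while its other concentrations gave at most 2 calls. Dapma7bEVm019556_96084 rose from 2.58 ± 2.91 CPM (SD, n = 6) to 48 ± 21.6 (n = 3) at 2.113 µM, a log2 fold change of 4.06 ± 0.70 (SE; adjusted p = 0.00382, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). At 66.67 µM the same probe stood at 0.754 ± 1.31 CPM. With the co-tested 2-tert-butyl-4-methoxyphenol, against the DMSO pools of the same exposure, it rose at 0.212 µM to 44.1 ± 31.2 CPM (n = 3). The log2 fold change there was 3.99 ± 0.77 (adjusted p = 0.00742, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Both contrasts used the same 6 DMSO pools. All calls of 2-tert-butyl-4-methoxyphenol at 0.212 µM went to 0 without replicate B, without C or against the CON pools alone. Whether the rise was particular to Metribuzin-DA is therefore not settled. Dapma7bEVm003644_96155 fell from 248 ± 121 to 21.8 ± 18.8 CPM at 2.113 µM (log2 fold change -3.50 ± 0.93). The calls at the 2 concentrations had 4 higher and 1 lower probe in common, against 1.92 and 0.147 for independent lists. The 20 simulations of unchanged counts shared 0 and, without any changed probe, do not test shared controls. With CON and XtraC pools apart, 0 or 1 higher and 0 lower probes were shared. In both directions together 5 were shared; with the replicate letter in the model there were 8, 11 in DESeq2, 8 without replicate A, 0 without B or without C, 1 against the CON pools alone and 0 in limma on the chemical's own table.

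The counts for Metribuzin-DA changed with 1 replicate left out and against the CON pools alone. Both leave fewer libraries, so a lower count alone does not show dependence on particular pools. At 2.113 µM 47 probes were called without replicate A, 14 without B, 18 without C and 23 against the CON pools alone; at 0.067 µM the counts were 194, 0, 0 and 2. Over all levels they were 116, 1, 2 and 5. The fall of Dapma7bEVm003644_96155 missed the threshold without replicate B, without C and against the CON pools alone.

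The remaining 7 chemicals changed few probes or none. Gabapentin, an anticonvulsant, changed 8 of 1440 probes (DESeq2 32), 1(2H)-phthalazinone 3 of 1443 (DESeq2 37, and 22 with the replicate letter in the model), fexofenadine 3 of 1390 (DESeq2 6, and 0 with the replicate letter) and 4-chlorophenyl methyl sulfoxide 1 of 1429 (DESeq2 26, and 4 with the replicate letter). Metolachlor OA, a breakdown product of the herbicide metolachlor, gave 0 of 1418 in the edgeR test (91 at an unadjusted p under 0.05, DESeq2 12). Hydrochlorothiazide, a diuretic, gave 0 of 1418 (56 at an unadjusted p under 0.05, DESeq2 0), and the antihistamine cetirizine 0 of 1379 (117 at an unadjusted p under 0.05, DESeq2 14, and 4 with the replicate letter). In counts simulated from the hydrochlorothiazide libraries, the any-level test recovered 14.9% of probes changed 1.5-fold at the highest concentration alone, 59.7% of those changed 2-fold and 72.7% of those changed 3-fold.

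Pools differed widely in the largest values among these 7 chemicals. With gabapentin at 66.67 µM, Dapma7bEVm006156_97378 averaged 104 ± 97.6 CPM (SD, n = 3) against 4.82 ± 4.98 in DMSO (n = 6), a log2 fold change of 4.42 ± 0.72 (SE; adjusted p = 0.00341, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Its 3 pools ran from 11.6 to 206, and it missed the threshold without replicate B, without C, against the CON pools alone and in limma on the chemical's own table. With gabapentin at 0.669 µM, Dapma7bEVm009468_97463 averaged 230 ± 383 CPM (SD, n = 3) against 6.53 ± 8.28 in DMSO (n = 6), and its 3 pools ran from 6.91 to 673. With fexofenadine at 34.2 µM, Dapma7bEVm007743_97113 averaged 488 ± 785 CPM against 31.4 ± 27.2 in DMSO, its pools ran from 25.6 to 1394, and without replicate A its log2 fold change went from 3.92 to -0.17 (adjusted p = 0.999, edgeR quasi-likelihood with Benjamini-Hochberg adjustment; 0.0257 with all replicates). Calls at single levels, with at most 1 call at any higher concentration, were 16 higher and 6 lower for Metolachlor OA at 0.021 µM. For cetirizine they were 13 higher and 2 lower at 6.677 µM. Leaving out any replicate left at most 1 call of Metolachlor OA and 0 of cetirizine at these levels, against the CON pools alone both were 0, and with the replicate letter in the model they were 123 and 97.

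The second question was how far the responses overlapped between chemicals of different exposures, which share no DMSO pools. Probes called in at least 1 exposure numbered 765, those in 2 or more 227, in 3 or more 60 and in 4 exposures 8. Of these 8, 7 were called for fipronil amide, cis-nonachlordane, 3,4-dichlorophenyl isocyanate and 2-tert-butyl-4-methoxyphenol alike, each in 1 direction over all 4 chemicals. Dapma7bEVm002921_97205 was higher and Dapma7bEVm011534_97824 lower in all 4. At the highest concentration, Dapma7bEVm002921_97205 had log2 fold changes of 3.27 with fipronil amide, 1.28 with cis-nonachlordane, 3.61 with 3,4-dichlorophenyl isocyanate and 5.63 with 2-tert-butyl-4-methoxyphenol; with Metribuzin-DA it stood at 0.20 ± 0.52 and was not called.

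**Figure D3:**
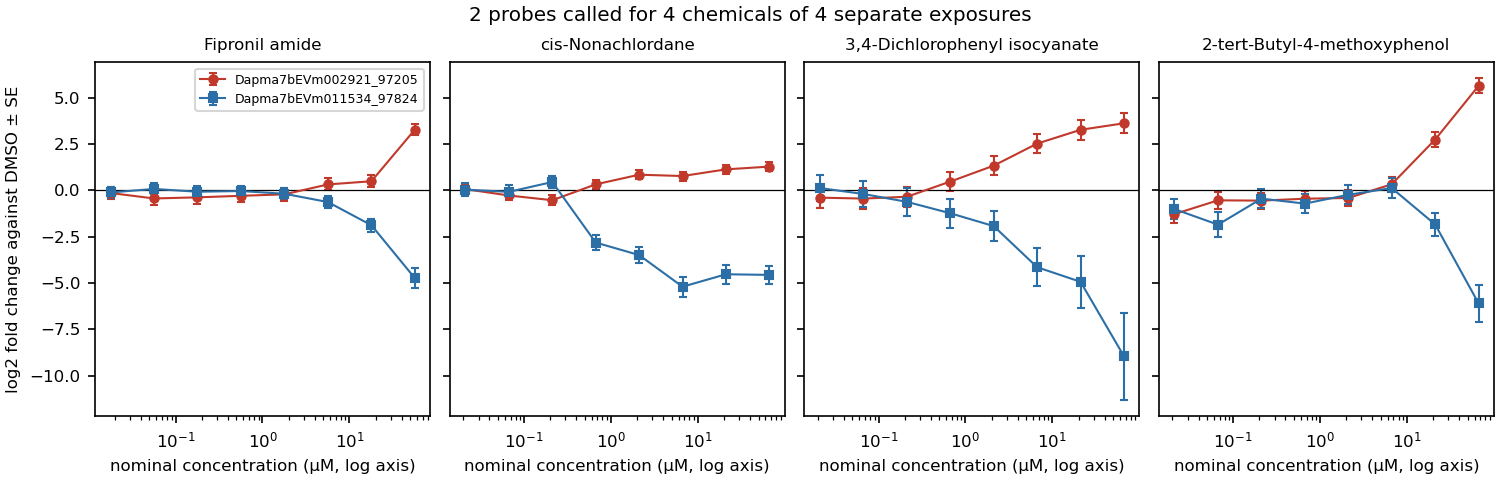
Log2 fold change against DMSO (y axis, points with SE) of Dapma7bEVm002921_97205 and Dapma7bEVm011534_97824 over the nominal concentrations (x axis, µM, log scale) of 4 chemicals. The former reaches 5.63 with 2-tert-butyl-4-methoxyphenol; the latter lies between -5.20 and -2.82 over the 5 highest concentrations of cis-nonachlordane, and its point for 3,4-dichlorophenyl isocyanate at 66.67 µM is a fitted value of a group with 0 counts.

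The number of shared probes was highest for 2-tert-butyl-4-methoxyphenol, the chemical with the most calls. It shared 53 higher probes (16.8 for independent lists) and 25 lower (7.43) with fipronil amide, with 7 opposite, and 46 higher (21.9) and 61 lower (17.8) with cis-nonachlordane, with 31 opposite. With 3,4-dichlorophenyl isocyanate it shared 39 higher probes (16.7) and 4 lower (2.00), with 9 opposite. Fipronil amide and cis-nonachlordane shared 17 higher (3.80) and 16 lower (2.36), with 2 opposite, and fipronil amide and 3,4-dichlorophenyl isocyanate 14 higher (2.73) and 4 lower (0.268), with 2 opposite. cis-Nonachlordane and 3,4-dichlorophenyl isocyanate shared 9 higher (3.55) and 2 lower (0.690), with 10 opposite. Metribuzin-DA shared 9 higher (1.86) and 0 lower probes (0.155) with 3,4-dichlorophenyl isocyanate, with 0 opposite, and 0 higher and 0 lower with fipronil amide (1.82 and 0.589 for independent lists), with 5 opposite. With cis-nonachlordane it shared 1 higher (2.41) and 1 lower (1.39), with 11 opposite. Among 18 two-sided Fisher's exact tests, 1 per pair and direction, the Benjamini-Hochberg adjusted p was 1.17e-23 for the lower probes of cis-nonachlordane and 2-tert-butyl-4-methoxyphenol, 1.62e-21 for the higher probes of fipronil amide and 2-tert-butyl-4-methoxyphenol, 0.000103 for the higher probes of Metribuzin-DA with 3,4-dichlorophenyl isocyanate, 0.0115 for the higher probes of cis-nonachlordane with it and 0.329 for the higher probes of Metribuzin-DA with fipronil amide. Probes are not independent of each other, so these p-values describe overlap across probes. Without replicate C of 3,4-dichlorophenyl isocyanate at 21.1 µM, an alternative chosen after the overlaps were seen, the isocyanate shared 1 higher probe with Metribuzin-DA (1.86 for independent lists) and 7 with cis-nonachlordane (3.73). It still shared 15 with fipronil amide (2.87) and 39 with 2-tert-butyl-4-methoxyphenol (17.5); the adjusted p over 8 tests was 1, 0.186, 1.28e-07 and 8.06e-08. The count of probes called in 2 or more exposures was 351 with the replicate letter in the model, 69 to 131 with 1 replicate left out and 77 with limma on the chemicals' own tables.

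The third question was the concentration at which transcripts depart from the DMSO pools. A benchmark concentration, where a probe's fitted curve leaves the DMSO level by 1 SD of the DMSO pools, had a 10th percentile over probes of 0.171 µM and a median of 0.414 µM for cis-nonachlordane, over 158 of its 173 called probes, the lowest values among the chemicals' probes with a value inside the tested range. For 3,4-dichlorophenyl isocyanate these were 0.228 and 1.32 µM (62 of 73 probes), for fipronil amide 3.82 and 11.4 µM (100 of 100) and for 2-tert-butyl-4-methoxyphenol 6.75 and 17.9 µM (662 of 680). These are read from fitted curves, and few probes were called at tested concentrations nearby. Fipronil amide had 4 calls at 17.9 µM and 0 at 5.65 µM, against 219 at 56.43 µM. 2-tert-Butyl-4-methoxyphenol had 25 at 21.1 µM and 1 at 6.677 µM, against 761 at 66.67 µM. 3,4-Dichlorophenyl isocyanate had 1 at 2.113 µM and 0 at 0.669 µM. The order of cis-nonachlordane and 3,4-dichlorophenyl isocyanate was not the same throughout: over the probes of the trend test the 10th percentiles were 0.171 and 0.155 µM, and without replicate A 0.150 and 0.137 µM, while the medians stayed lowest for cis-nonachlordane. For Metribuzin-DA they were 0.273 and 3.84 µM, but over 41 of 71 probes, and its calls at 2.113 and 0.067 µM with at most 2 above 2.113 µM are not described by curves that only rise or only fall. Below the tested range lay 10 further probes of Metribuzin-DA, 4 of cis-nonachlordane and 6 of 2-tert-butyl-4-methoxyphenol. With probes outside the range counted as lowest or highest, an alternative chosen after the values were seen, the 10th percentile of Metribuzin-DA (53 probes) lay below the range and that of cis-nonachlordane (164 probes) was 0.148 µM, with medians of 2.59 and 0.413 µM. With a departure of 2 SD the medians were 0.579, 2.5, 21.9 and 32.5 µM for cis-nonachlordane, 3,4-dichlorophenyl isocyanate, fipronil amide and 2-tert-butyl-4-methoxyphenol, over 118 of 173, 59 of 73, 96 of 100 and 635 of 680 probes. For 45 probes of cis-nonachlordane the fitted curve stayed under 2 SD up to the highest tested concentration. On simulated curves the quartiles of single-probe estimates were 0.670 and 2.03 times a true value of 0.5 µM. They were 0.471 and 1.77 times 5 µM, and 0.590 and 1.62 times 20 µM. Those curves had a single saturating shape and equal spread in all pools, while treated pools varied more than DMSO pools (median SD 0.38 against 0.25 log2). This accuracy may therefore not carry over to the probes here. Differences between chemicals in these concentrations were not tested.

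**Figure D4:**
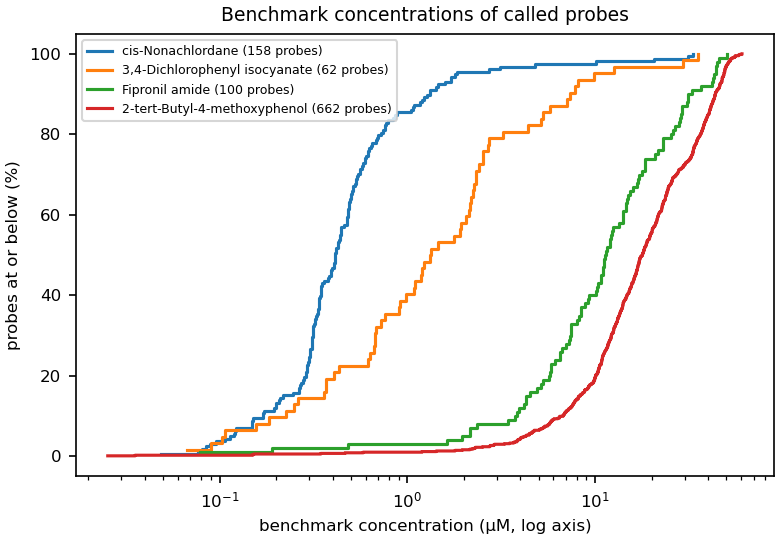
Cumulative percent of the called probes with a benchmark concentration inside the tested range (y axis) against that concentration (x axis, µM, log scale) for 4 chemicals, 1 line each. Called probes without such a value are left out. The medians are 0.414 µM for cis-nonachlordane, 1.32 µM for 3,4-dichlorophenyl isocyanate, 11.4 µM for fipronil amide and 17.9 µM for 2-tert-butyl-4-methoxyphenol.

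Cetirizine and fexofenadine are both H1 antihistamines, tested in different exposures, and were compared as changes against their own DMSO pools at the same level code. The concentrations differed: 66.67 against 34.2 µM at D1 and 0.021 against 0.0108 µM at D8. No probe differed between them at an adjusted p under 0.05: edgeR's test over all levels called 0 of 1425 probes, with 49 at an unadjusted p under 0.05, and each level called 0, with 21 to 123 at an unadjusted p under 0.05. No other tool was run for this comparison. The median size of the difference was 0.14 to 0.22 log2 per level and at the median its 95% interval reached 0.55 to 0.56 log2 to either side. The interval lay within 1 log2 in 62.7% to 67.2% of probes, so for the others a difference of that size was not excluded.

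The DMSO pools differed between exposures, where the animals, their handling and the libraries cannot be told apart. Over the 36 DMSO pools, 992 of 1397 probes differed between the 6 exposures (DESeq2 988, and 646 with the CON pools alone), at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Within exposures the 18 CON pools and the 18 XtraC pools, the names the labels give to the DMSO pools, differed at 0 of 1316 probes (99 at an unadjusted p under 0.05; no other tool was run). The 12 control QA libraries under their 4 codes differed at 0 of 1333 probes (43 at an unadjusted p under 0.05; no other tool was run). The median SD of log2 CPM over 1272 probes was 0.18 among QA libraries of 1 code, 0.25 among DMSO pools of 1 exposure and 0.38 among treated pools of 1 chemical and concentration.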

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

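The tests of a low total count, of few probes in replicate C of 3,4-dichlorophenyl isocyanate at 21.1 µM, of library size and of a deviation shared with the co-tested chemical for Metribuzin-DA, and of a chance pairing of levels were chosen after the result was seen. Among the 36 sets of 6 DMSO pools and measures tested for a pool standing apart from the others, 0 held such a pool, where chance gives about 1 in 20.

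Replicate C of 3,4-dichlorophenyl isocyanate at 21.1 µM held 74.8% of its 118094 counts in 1 probe. A low total count alone is argued against: of the 5 libraries with the next lowest totals (167462 to 227676), 0 had a share of the 10 most counted probes over 35.3%, the limit of 3 SD over the median, and theirs were 29.2% to 33.8%. A few probes crowding out an otherwise usual library is argued against too, since without its 10 most counted probes its correlation with the median of the other libraries, across 1444 probes, was 0.667, below the 0.830 to 0.889 of the other libraries thinned to the same 9798 counts, in each of 20 thinnings. A shift of replicate C by 1 level is argued against at the 3 levels tested, as 0 of them lay closer to replicates A and B of 1 level higher, over 16 probes. What made this library differ stays open.

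Metribuzin-DA had 165 calls at 2.113 µM and 34 at 0.067 µM, but at most 2 at higher concentrations than 2.113 µM. For 2.113 µM, a difference in library size is argued against, since the mean total of 807544 counts lay within the 581870 to 828800 of the other levels. So is a deviation shared with 2-tert-butyl-4-methoxyphenol at the same level, with a correlation of 0.224 across 163 probes. With that chemical's level D6 the correlation was 0.751, so a deviation shared across unlike levels of the exposure stays open and was not tested. An axis of variation also present among untreated pools may account for part of these calls: across 158 probes the fold changes correlated at 0.605 in size with the first principal component (23.1% of variance) of the 30 DMSO pools of the other exposures. For 0.067 µM, the mean total of 466088 counts lay below those of the other levels and the deviation was shared with the co-tested chemical at the same level (0.886 across 32 probes, against 0.667 at its level D6), so both stay candidate explanations, while the correlation of 0.353 with the untreated axis across 22 probes did not decide. An effect of the chemical at these concentrations, the biological explanation in the design, stays open and was not tested apart from these.

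Libraries of 2 co-tested chemicals deviated together at the same level on average: the mean correlation across probes of their deviations from each chemical's own mean over levels was 0.102 over 48 pairs, with 17 pairs under 0 (lowest -0.482) and 10 over 0.3. The mean for different levels, -0.0138, largely follows from taking deviations from the mean over levels and is no separate evidence. A chance pairing of levels is argued against (one-sided permutation p = 0.00429, 100000 shuffles). So are the handling of 1 replicate plate, since the mean for libraries of the same letter minus that for different letters was -0.0078 (143 and 286 library pairs), and library size, since regressing out the total changed the mean by -9.44%, where a negative value is a rise. For the plate test deviations were taken from each letter's own mean, so it speaks only to handling that differed between levels of a plate. None of these deviations uses a DMSO pool, and the source of the pattern stays open. No biological explanation was tested, since the design gives none.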

How the results depend on the processing

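The alternatives that left out libraries under 50% of the median total, replicate C of 3,4-dichlorophenyl isocyanate at D2, or level D1, D4 or D7 from the any-level test, that used the concentration line of that chemical's own table, that split the DMSO pools between 2 levels, that left replicates out of the benchmark concentrations, or that recomputed the overlaps of 3,4-dichlorophenyl isocyanate or the splits at single levels, or that counted probes outside the range in the benchmark concentrations, were chosen after seeing the data. DESeq2's size factors and keeping all libraries moved 0 of the 12 any-level and 0 of the 12 trend counts by over 1.5 times; the latter removes nothing, since 0 libraries were under 10% of the median. The gene lists and their alternatives were not run, for want of gene names. Except where the construction of an alternative is named, the cause was not tested.

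With DESeq2 in place of edgeR, the any-level counts were 12 for Metolachlor OA, 166 for fipronil amide, 6 for fexofenadine, 119 for 3,4-dichlorophenyl isocyanate, 37 for 1(2H)-phthalazinone, 32 for gabapentin, 261 for Metribuzin-DA, 26 for 4-chlorophenyl methyl sulfoxide and 14 for cetirizine. The trend counts were 5 for fexofenadine, 117 for 3,4-dichlorophenyl isocyanate, 2 for gabapentin, 3 for 4-chlorophenyl methyl sulfoxide and 10 for cetirizine, and 359 probes were called in 2 or more exposures. The other 3 any-level and 7 trend counts stayed within 1.5 times.

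With the replicate letter in the model, the any-level counts were 175 for fipronil amide, 0 for fexofenadine, 272 for cis-nonachlordane, 22 for 1(2H)-phthalazinone, 4 for 4-chlorophenyl methyl sulfoxide and 4 for cetirizine, the trend count of fexofenadine was 0, and 351 probes were called in 2 or more exposures. The other 6 any-level and 11 trend counts stayed within 1.5 times. With both chemicals of an exposure in 1 fit, the counts were 1 for fexofenadine, 116 for 3,4-dichlorophenyl isocyanate, 13 for 1(2H)-phthalazinone, 107 for Metribuzin-DA, 3 for hydrochlorothiazide, 0 for 4-chlorophenyl methyl sulfoxide and 3 for cetirizine, and the other 5 stayed within 1.5 times.

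With limma on the chemicals' own log2 tables, which are not scaled for the library total, the counts were 214 for fipronil amide, 0 for fexofenadine, 11 for 3,4-dichlorophenyl isocyanate, 0 for 1(2H)-phthalazinone, 0 for gabapentin, 12 for Metribuzin-DA, 119 for 2-tert-butyl-4-methoxyphenol and 0 for 4-chlorophenyl methyl sulfoxide, and 77 probes were called in 2 or more exposures. Higher and lower probes at single levels were 39 and 68 for fipronil amide at D1, and 1 and 6, 15 and 1163, and 4 and 1 for 3,4-dichlorophenyl isocyanate at D1 to D3. For cis-nonachlordane at D1 to D5 they were 24 and 5, 102 and 12, 28 and 8, 43 and 8, and 53 and 4, for Metribuzin-DA 9 and 4 at D4 and 0 and 2 at D7, and for 2-tert-butyl-4-methoxyphenol 84 and 115 at D1. Against the CON pools alone, which leaves 3 controls, the counts were 1 for fexofenadine, 115 for cis-nonachlordane, 1 for gabapentin, 5 for Metribuzin-DA and 1 for cetirizine. Between exposures the CON pools differed at 646 probes, and the 96 single-level tests gave 1053 calls in place of 1894. Without the filter on low counts the count for 1(2H)-phthalazinone was 9, and the trend counts were 5 for fexofenadine and 2 for 4-chlorophenyl methyl sulfoxide.

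Leaving out each replicate letter in turn, which leaves fewer libraries, gave any-level counts of 24 to 80 for fipronil amide, 0 to 0 for fexofenadine, 24 to 91 for cis-nonachlordane, 16 to 80 for 3,4-dichlorophenyl isocyanate, 0 to 1 for 1(2H)-phthalazinone, 0 to 4 for gabapentin, 1 to 116 for Metribuzin-DA, 318 to 698 for 2-tert-butyl-4-methoxyphenol and 0 to 0 for 4-chlorophenyl methyl sulfoxide. The trend counts were 12 to 97 for fipronil amide, 0 to 5 for fexofenadine, 46 to 89 for cis-nonachlordane, 1 to 99 for 3,4-dichlorophenyl isocyanate and 42 to 417 for 2-tert-butyl-4-methoxyphenol. Probes called in 2 or more exposures numbered 69 to 131, calls of the single-level tests 886 to 1853, and probes differing between DMSO pools of different exposures 791 to 891. Leaving out each control QA library gave 0 to 5 calls, 5 without the C12 well of DM001 and 1 without the G1 well of DM003. Dapma7bEVm007743_97113, called with fexofenadine at D1, had a log2 fold change of 3.92 with all replicates, and -0.17 to 5.23 with 1 left out (-0.17 without replicate A, adjusted p = 0.999; over its alternatives 0.00156 to 0.999).

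The benchmark concentrations with each replicate left out had 10th percentiles of 2.72 to 3.32 µM for fipronil amide, 0.115 to 0.150 for cis-nonachlordane, 0.137 to 0.265 for 3,4-dichlorophenyl isocyanate, 0.184 to 0.737 for Metribuzin-DA and 4.47 to 6.57 for 2-tert-butyl-4-methoxyphenol. The medians were 8.87 to 12.5, 0.314 to 0.396, 1.21 to 1.42, 3.82 to 4.02 and 13.4 to 22.9 µM; Metribuzin-DA without replicate B had 16 probes with a value, and none is given. With a departure of 2 SD, which lies farther along each curve, the 10th percentiles were 8.36, 0.312, 0.832, 0.686 and 12.8 µM and the medians 21.9, 0.579, 2.5, 4.49 and 32.5 µM, for the same chemicals in turn, over 96 of 100, 118 of 173, 59 of 73, 31 of 71 and 635 of 680 probes. Over the probes called in the trend test the 10th percentiles were 1.62 µM for fipronil amide and 0.155 µM for 3,4-dichlorophenyl isocyanate, below the 0.171 µM of cis-nonachlordane, and the medians 0.542 µM for cis-nonachlordane and 0.916 µM for 3,4-dichlorophenyl isocyanate. With probes below the range counted as lowest and those above it as highest, the 10th percentiles were 3.73 µM for fipronil amide, 0.148 for cis-nonachlordane, 0.225 for 3,4-dichlorophenyl isocyanate and 5.98 for 2-tert-butyl-4-methoxyphenol, and that of Metribuzin-DA lay below the range. Without replicate A the 10th percentile of 3,4-dichlorophenyl isocyanate, 0.137 µM, was again below that of cis-nonachlordane, 0.150 µM.

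Without level D1 the any-level count of 2-tert-butyl-4-methoxyphenol was 30, and the trend counts were 3 for fipronil amide, 0 for fexofenadine and 9 for 2-tert-butyl-4-methoxyphenol. Without D8 the trend counts were 184 for fipronil amide and 645 for 2-tert-butyl-4-methoxyphenol. The any-level count of Metribuzin-DA was 6 without D4, 45 without D7 and 47 without libraries under 50% of the median total, where its trend count was 1 and the any-level count of 1(2H)-phthalazinone 5. With the replicate letter in the model and replicate C at D2 left out, 3,4-dichlorophenyl isocyanate had 167 any-level and 131 trend calls. With that library left out, its calls shared 1 higher probe with Metribuzin-DA in place of 9, 7 with cis-nonachlordane in place of 9, 15 with fipronil amide in place of 14 and 39 with 2-tert-butyl-4-methoxyphenol in place of 39.

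Of 24 pairs of probe and chemical followed through the alternatives, 1 of them chosen after its values were seen and not all of them printed, 22 stayed past the threshold with the replicate letter in the model, 15 of 23 against the CON pools alone, 20 without replicate A, 17 without B and 14 of 23 without C. Limits: 3 pools per concentration in 1 exposure each, totals of 118094 to 1171681 counts, and recovery in simulated counts of 1.49% (2-tert-butyl-4-methoxyphenol) to 37.3% (fexofenadine) for a 1.5-fold change at the highest concentration alone, with 4.48% for 3,4-dichlorophenyl isocyanate and 5.97% for Metribuzin-DA, so smaller changes and probes of few counts were often out of reach.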

Other observations

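The test that probes of 1 gene move together was chosen before its result was seen; the single-level splits were chosen after the level counts were seen, their count over any of 8 levels and those without the libraries of D1 after the splits were seen, and the other splits before theirs were.

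Probes of the same gene identifier moved together over the concentrations. For genes with 2 or more probes and a called one, the median correlation of the log2 fold changes over the 8 levels was 0.695 over 186 probe pairs, 109 of them over 0.5 and 49 under 0. Random pairs gave medians of -0.187 to 0.193 (95% of 10000 sets). Probes are not independent replicates.

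Other splits of the libraries tested whether the any-level counts could come by chance, with 100 splits within the replicate letter, the real one included. As many calls as the real split came in 1 of 100 splits for fipronil amide (100 calls, highest other 16), cis-nonachlordane (173 and 5), 3,4-dichlorophenyl isocyanate (73 and 28) and 2-tert-butyl-4-methoxyphenol (680 and 544), so chance is excluded there at a share under 0.05. For Metribuzin-DA they also came in 1 of 100 (71 and 20), but its count was 1 to 116 with 1 replicate left out, so chance stays open there. A split of its libraries gave 352 calls in the trend test, a different test that does not bear on this count. For 1(2H)-phthalazinone as many calls came in 3 splits (3 and 5), but splits regardless of the letter gave as many in 7 of 100, with 79 as the highest. Leaving out a replicate left 0 or 1 call, so chance stays open there too. It is not excluded for fexofenadine (5 splits; 3 and 8), gabapentin (8 splits; 8 and 27) and 4-chlorophenyl methyl sulfoxide (72 splits; 1 and 6). With 0 real calls all 100 splits gave as many for Metolachlor OA (highest other 3), hydrochlorothiazide (12) and cetirizine (8). Regardless of the letter, the highest for hydrochlorothiazide was 136, which points to a structure of its libraries.

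In the trend test as many calls came in 1 of 100 splits for fipronil amide (91 calls, highest other 2) and cis-nonachlordane (122 and 32). The same held for 2-tert-butyl-4-methoxyphenol (399 and 316), so chance is excluded for these chemicals. For 3,4-dichlorophenyl isocyanate they also came in 1 of 100 (75 and 15). Its trend count was 1 to 99 with 1 replicate left out, so chance stays open there. For fexofenadine they came in 5 (3 and 5), where chance is not excluded. With 0 real calls all 100 splits gave as many for Metolachlor OA (highest other 1), 1(2H)-phthalazinone (7), gabapentin (6), Metribuzin-DA (352), hydrochlorothiazide (1), 4-chlorophenyl methyl sulfoxide (1) and cetirizine (3). The 352 calls of a split of Metribuzin-DA, and the 159 and 196 of splits of 1(2H)-phthalazinone and gabapentin regardless of the letter, point to a structure of those libraries. For fipronil amide a split regardless of the letter reached 88 calls, near its 91, though only the real one gave as many.

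At single levels as many calls came in 1 of 100 splits for Metolachlor OA at D8 (22 calls, highest other 1), fipronil amide at D1 (219 and 35), cis-nonachlordane at D1 (45 and 12), D2 (104 and 1), D3 (57 and 4), D4 (106 and 2), D5 (60 and 5) and D8 (10 and 5), 3,4-dichlorophenyl isocyanate at D2 (54 and 20) and D3 (51 and 26), Metribuzin-DA at D4 (165 and 70) and D7 (34 and 6), 2-tert-butyl-4-methoxyphenol at D1 (761 and 231) and cetirizine at D3 (15 and 8). For 2-tert-butyl-4-methoxyphenol they came in 4 splits at D6 (33 and 495), 5 at D2 (25 and 402) and 7 at D7 (70 and 759). These highest counts, several times the real ones, point to a structure of the samples: the splits move libraries of D1, with 761 calls, into other groups.

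These levels were picked out of 96 for their counts, and the splits at 1 level make no allowance for that. Counting a split when any of the chemical's 8 levels had as many calls, which allows for the 8 levels but not for the 12 chemicals, gave 6 of 100 splits for Metribuzin-DA at D7 (highest other 98), where chance is not excluded. For 2-tert-butyl-4-methoxyphenol at D2, D6 and D7 the splits hold the response at D1 and do not test chance, so they were repeated without the libraries of D1. As many calls then came in 2 of 100 splits at D2 (25 calls, highest other 64), 2 at D6 (23 and 91) and 1 at D7 (52 and 33), and at any of the 7 levels left in 5, 5 and 4. Calls with a replicate left out numbered 8 to 23 at D2, but at D6 and D7 went to 0 without replicate B or C, so chance stays open at D6 and D7, while at D2 the splits alone do not settle it. Over any of 8 levels the count was 2 for Metolachlor OA at D8 (100) and 1 for cetirizine at D3 (9), but with 0 any-level calls for both chemicals, and with at most 1 and 0 calls with any 1 replicate left out, chance stays open there too. The count was 2 for cis-nonachlordane at D8 (12) and 2 for 2-tert-butyl-4-methoxyphenol at D1 (770), and 1 at each of the other levels named (highest other 12 to 98), all of chemicals whose any-level counts exceed every other split. At D8 the calls of cis-nonachlordane went to 0 without replicate B or C, so chance stays open at that level. For Metribuzin-DA chance stays open over all levels, as given above.

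For the untreated libraries, as many probes as between the 6 exposures came in 1 of 100 splits of the DMSO pools (992 and 65), so chance is excluded. With 0 real calls all 100 splits gave as many between CON and XtraC pools (highest other 1), between the codes of the control QA libraries (85) and between cetirizine and fexofenadine (0). The QA split with 85 calls put both A12 wells in 1 group and both C12 wells in another, and points to a structure of those libraries.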
